A study of Danio rerio with 17 samples.

How the data were processed

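The libraries came from zebrafish embryos of 3 transgenic lines that had been dissociated and sorted by fluorescence, per the labels at 4 days post fertilization for the acta2 and acta2/foxc1b lines and at 5 days for the kdrl line. Per the labels, RNA was extracted with TRIzol. For the acta2 and acta2/foxc1b lines the cDNA, primed with oligo dT, was amplified with REPLI-g and given TruSeq adapters, whereas kdrl cells were fixed before sorting and their libraries were made with the TotalScript kit. The tools that the submitters list are bcl2fastq 2.14, CASAVA 1.8.2, featureCounts 1.5.2 and DESeq2 1.20.0, with genome build GRCz11; the aligner and the annotation are not given in the sources used here. Raw reads were not used here.

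The deposited table holds, for 30220 genes and 17 libraries, a signal value per gene and library, which is a read count that the authors divided by a size factor of the library. In each library all values were whole multiples of a single step, within a tolerance of 0.1 read, so that 100% of the values gave back whole reads. The row means of the 11 acta2 and acta2/foxc1b libraries equaled the deposited baseMean to within a relative difference of 6.27e-07, and those of the 6 kdrl libraries their own baseMean to within 2.62e-09, so the sets were scaled apart. The authors also deposited a log2 fold change and a p-value with its adjusted form for each of the 3 comparisons; whether these fold changes were shrunken is not stated. In the deposited adjusted p, 573 genes were higher and 757 lower of 23542 in the acta2 line, 1247 and 1521 of 24115 in the acta2/foxc1b line, and 1519 and 1509 of 22798 in the kdrl line. Of the calls made here, 971 of 1441, 6 of 6 and 1483 of 1485 were also called there in the same direction.

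Reads of polymerase-amplified cDNA without molecular identifiers are not independent molecules, so the share of counting error in the spread between libraries is unknown. Samples were grouped by their titles into positive and negative cells of each line. Whether replicate numbers pair a positive with a negative library was checked by correlating, across genes, their deviations from the group means. In the kdrl line libraries of the same number correlated at 0.475, 0.128 and 0.422, above all other pairs, so blocked values are given beside that result. In the acta2 line they correlated at 0.01, -0.023 and -0.014, and in the acta2/foxc1b line at 0.144 and 0.056 for 2 pairs, and these lines were treated as unpaired.

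Because the deposited values are normalized, the count test planned for a table of counts was replaced by its planned substitute. Genes with a value of at least 10 in as many libraries as the smaller group were tested by limma-trend on log2(value + 1), with robust settings off, moderated across genes, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the call. Each line was fitted alone. Differences of sort effects, positive minus negative in a line minus the same in another, were fitted over the 11 libraries of both acta2 lines and over the 12 libraries of the acta2 and kdrl lines. Shared calls were tested by two-sided Fisher's exact test, adjusted over the 4 tests that could be made. Programs were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

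Gene lists, 28 in number, were fixed before the data were examined, as were the comparisons, their main tests, the rule for naming genes and most alternatives. The lists were smooth muscle contractile, pericyte and mural, endothelial, head mesenchyme and neural crest transcription factors, extracellular matrix, TGF-beta and BMP pathway, Notch pathway, Hedgehog pathway, Wnt pathway, PDGF and VEGF ligands and receptors, skeletal muscle, cardiac muscle, neuron, neural progenitor and glia, photoreceptor and retina, lens, epidermis, erythroid, leukocyte, liver gut and exocrine pancreas, pigment cell, cartilage and bone, tendon and fibroblast, cell cycle, dissociation and stress response, cytosolic ribosomal proteins, mitochondrially encoded genes, and ion channels and calcium handling of smooth muscle. Symbols were matched to the table directly or through the synonyms in the reference tables; 42 of 46 smooth muscle contractile, 60 of 65 endothelial and 57 of 58 skeletal muscle symbols matched. Each list was tested by camera with a preset correlation of 0.01 on the log2(value + 1) values, in place of log2 CPM, beside camera with an estimated correlation and fry; adjustment was over the 28 lists of a comparison. Counts within a list are given over all genes tested and adjusted over the list alone.

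Genes were named by rule: the 3 reporter genes; for each line the 10 called genes with the largest and the 6 with the most negative log2 fold change among those with a gene symbol that is not a clone or locus name, a mean of at least 100 normalized read counts in the higher group and no overlap between groups; for each list up to 4 called members with the smallest adjusted p, or up to 2 members with the smallest p where none was called; and for each difference of sort effects 6 per direction. Members of the lists that are only counted were left out. Gene positions are not given, since the reference table follows another genome build.

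Alternatives fixed beforehand were quantile normalization, DESeq2 on the recovered reads, array weights, no filter, all 17 samples in 1 fit, replicate number as a block, each library left out in turn, a fold change of at least 2, pseudocounts of 0.5 and 5, and direct comparison of positive groups. Added after the data were seen were the edgeR quasi-likelihood test on recovered reads with TMM scaling, limma on TMM-scaled reads, counts within lists, fry and an estimated correlation under the block, and leaving out each library for the lists other than smooth muscle contractile, pericyte and mural, and endothelial. The tools were also tested on simulated data, reads drawn with the means and dispersions estimated from the same libraries, in which 200 genes were changed by 2, 4, 8 or 16-fold. At 8-fold, limma recovered 66% in the acta2 design, with 4.94% of its calls on unchanged genes, and 66% in the kdrl design, with 2.20%. In the acta2/foxc1b design limma recovered 0% even at 16-fold, as did edgeR, while DESeq2 recovered 56% at 16-fold, with 72.5% of its calls on unchanged genes. In the difference between the acta2 lines limma recovered 8% at 16-fold, and in that between the acta2 and kdrl lines 20%. Camera called 0 of 40 unchanged and 10 of 10 changed simulated lists in each design, but simulated genes were not correlated, so this does not give its error rate here, where other acta2 splits called 5 to 20 lists.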

Results

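RNA sequencing profiled cells that had been sorted by fluorescence from dissociated zebrafish embryos of 3 transgenic lines, in 17 libraries that fell into 6 groups. In the acta2 line, Tg(acta2:egfp), a green fluorescent protein marks cells that use the promoter of acta2, the smooth muscle actin gene. This line gave 3 positive libraries of mural cells, the contractile cells that wrap vessels, and 3 negative libraries of the remaining cells at 4 days post fertilization. The acta2/foxc1b line, Tg(acta2:mcherry);(foxc1b:egfp), carries a further reporter for foxc1b, a forkhead transcription factor gene of head mesenchyme, and gave 2 positive and 3 negative libraries at 4 days. The kdrl line, Tg(kdrl:mcherry), reports kdrl, a VEGF receptor gene of endothelium, and gave 3 endothelial and 3 non-endothelial libraries at 5 days. The labels do not say which colors were gated in the acta2/foxc1b line, and nothing in them says that replicates came from separate clutches, so each p-value measures the spread between these samples, which may be technical.

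Libraries held 10474235 to 40868765 recovered reads and between 23590 and 29445 genes with at least 1 read. Reads ran from 24946634 to 30928333 in acta2 negative and 20304807 to 24009466 in acta2 positive libraries. In the acta2/foxc1b line they ran from 21709413 to 33526582 in negative and 23531119 to 23882533 in positive libraries, and in the kdrl line from 10474235 to 20617552 and 11601057 to 40868765. Within groups, log2 values of library pairs correlated across genes at Pearson r of 0.834 to 0.967, where genes are not independent replicates. The lowest values involved acta2/foxc1b negative replicate 2, whose mean r with its replicates was 0.836. The mitochondrial ribosomal RNA gene mt-rnr2 took 9.35 to 16.3% of the reads in acta2 positive libraries and 1.23 to 3.86% in acta2 negative libraries.

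The reporter genes acta2 (ENSDARG00000045180), foxc1b (ENSDARG00000055398) and kdrl (ENSDARG00000105215) were followed in every library. Transcripts of acta2 were higher in the positive cells of both acta2 lines and averaged 463 ± 348 normalized read counts (SD, n = 3) against 335 ± 106 (SD, n = 3) in the kdrl line, a log2 fold change of 0.03 (SE 0.70, adjusted p = 0.984). The foxc1b transcript averaged 1361 ± 872 normalized read counts (SD, n = 2) against 299 ± 104 (SD, n = 3) in the acta2/foxc1b line, a log2 fold change of 2.07 (SE 0.66) that did not pass the test (adjusted p = 0.3). In the acta2 line foxc1b averaged 1266 ± 815 normalized read counts (SD, n = 3) against 3421 ± 1822 (SD, n = 3), a log2 fold change of -1.46 (SE 0.52, adjusted p = 0.129), and in the kdrl line its log2 fold change was 0.33 (SE 0.48, adjusted p = 0.705). The kdrl transcript was higher in kdrl positive cells, and it did not pass the test elsewhere, with log2 fold changes of 1.36 (adjusted p = 0.078) in the acta2 line and 1.52 (adjusted p = 0.605) in the acta2/foxc1b line.

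**Figure D1:**
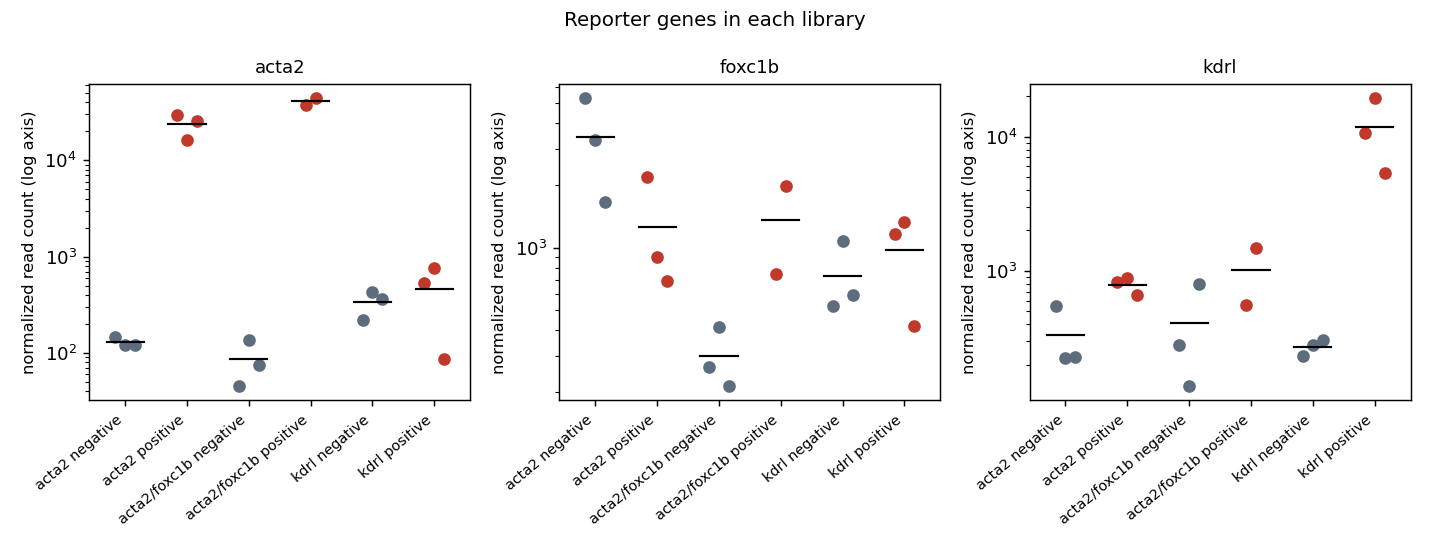
Normalized read counts on log axes of acta2, foxc1b and kdrl in each of the 17 libraries, with a point per library and a line at the group mean. The acta2 values of acta2 positive libraries lie between 16196 and 29672, all above the acta2 negative libraries, and the kdrl values of kdrl positive libraries lie between 5389 and 19330.

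Positive and negative cells of the acta2 line were compared to find the genes that mark the sorted acta2 reporter cells. Genes of the smooth muscle contractile and extracellular matrix lists were among those higher in the positive cells. The acta2 transcript was 177-fold higher, at 23849 ± 6922 normalized read counts (SD, n = 3) against 130.4 ± 14.8 (SD, n = 3), a log2 fold change of 7.46 (SE 0.31, adjusted p = 2.81e-05). Next came tagln, which encodes transgelin, an actin-binding protein of smooth muscle, with a log2 fold change of 6.22 (adjusted p = 0.0033), cnn1b, which encodes calponin, with 5.83 (adjusted p = 0.000695), and elnb, an elastin gene, with 5.83 (adjusted p = 0.00474). The largest named decrease was that of sst1.1, a somatostatin hormone gene, at 33.1 ± 10.9 normalized read counts (SD, n = 3) against 6451 ± 2908 (SD, n = 3) (log2 fold change -7.53, SE 0.42, adjusted p = 0.00022). Over 20582 tested genes, 670 were higher and 771 lower in positive cells.

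The smooth muscle contractile list held 41 measured genes and counted 25 higher and 0 lower over all genes, and 30 and 0 over the list alone (adjusted over it). The smooth muscle contractile list had a median log2 fold change of 2.19 (camera adjusted p = 7.11e-24, adjusted p = 0.0662 with an estimated correlation), and medians of lists given below are of the same kind. Members included myh11a, the smooth muscle myosin heavy chain gene (log2 fold change 5.11), lmod1b, a leiomodin that nucleates actin (5.30), and myl9a, a myosin light chain gene (4.39). Ion channel and calcium handling genes of smooth muscle had 6 of 38 higher and 1 lower, and 8 and 2 over the list alone, with a median of 0.70 (camera adjusted p = 0.00302, adjusted p = 0.0943 with an estimated correlation). Members included the cation channel gene trpc6a at 3.54. Pericyte and mural genes counted 6 higher and 0 lower over all genes, and 14 and 1 over the list alone, of 32, with a median of 0.92 (camera adjusted p = 1.47e-06, adjusted p = 0.0943 with an estimated correlation). They included notch3, the Notch receptor of mural cells (1.90), rasl12, a small GTPase gene (4.60), and cd248a, which encodes endosialin (2.28). Cardiac muscle genes, a list of 22, had 6 higher and 0 lower over all genes, and 11 and 1 over the list alone. The cardiac muscle list had a median of 1.55 (camera adjusted p = 9.86e-06, adjusted p = 0.0784 with an estimated correlation). Members included the transcription factor gene tbx20 at 3.18. Skeletal muscle genes counted 0 higher and 5 lower over all genes, and 0 and 7 over the list alone, of 54, and the list was not called. The skeletal muscle list had a median of -0.17 (camera adjusted p = 0.255), which moved by over 1.5 times with any library left out, over -0.38 to -0.07. The lower members included the myogenic regulators myog (-3.96) and myf5 (-3.13).

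Extracellular matrix genes had 27 of 83 higher and 0 lower, and 43 and 1 over the list alone, with a median of 1.01 (camera adjusted p = 9.29e-17, adjusted p = 0.0662 with an estimated correlation). The elastic fiber gene fbln5 had 21636 ± 3041 normalized read counts (SD, n = 3) against 1417 ± 251 (SD, n = 3) (log2 fold change 3.94), the crosslinking enzyme gene loxa 2.90 and the fibronectin gene fn1b 2.52. Head mesenchyme and neural crest genes had 10 higher and 1 lower over all genes, and 14 and 1 over the list alone, of 47, with a median of 0.66 (camera adjusted p = 0.000811, adjusted p = 0.199 with an estimated correlation). Cartilage and bone genes counted 4 higher and 1 lower over all genes, and 6 and 2 over the list alone, of 29, with a median of 0.30 (camera adjusted p = 0.0322, adjusted p = 0.46 with an estimated correlation). Tendon and fibroblast genes counted 3 higher and 0 lower over all genes, and 4 and 0 over the list alone, of 21, with a median of 0.28 (camera adjusted p = 0.0125, adjusted p = 0.236 with an estimated correlation). Pigment cell genes counted 2 higher and 0 lower over all genes, and 3 and 0 over the list alone, of 19, and were not called as a list. The pigment cell list had a median of 0.06 (camera adjusted p = 0.13), and the median turned negative without negative replicate 3, positive replicate 2 or positive replicate 3. The higher members were gch2 (3.77) and aox5 (4.99), both enzymes of pteridine pigment cells. Without acta2 positive replicate 1 the cartilage and bone list was not called (adjusted p = 0.244), and the medians were 0.39 for head mesenchyme and neural crest and 0.15 for tendon and fibroblast genes. Tendon and fibroblast genes had 0.43 without positive replicate 2 and 0.47 without positive replicate 3, and cartilage and bone genes 0.63 without positive replicate 2.

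TGF-beta and BMP genes counted 4 higher and 0 lower over all genes, and 7 and 0 over the list alone, of 60, with a median of 0.77 (camera adjusted p = 1.66e-06, adjusted p = 0.0943 with an estimated correlation). Members included the BMP pseudoreceptor gene bambia at 2.41. Notch genes counted 3 higher and 9 lower over all genes, and 5 and 10 over the list alone, of 32, and the list was not called. The Notch list had a median of -0.42 (camera adjusted p = 0.132). The delta ligand genes dla (-3.72) and dlb (-3.84) were lower while notch3 was higher, and the list was called without negative replicate 1 (-0.29, adjusted p = 0.0389), with medians of -0.08 without negative replicate 2, -0.17 without negative replicate 3 and -0.05 without positive replicate 3. Hedgehog genes counted 1 higher and 0 lower over all genes, and 4 and 0 over the list alone, of 17, with a median of 0.49 (camera adjusted p = 0.00286, adjusted p = 0.0943 with an estimated correlation). For Wnt genes the counts were 5 higher and 1 lower over all genes, and 11 and 1 over the list alone, of 54, with a median of 0.14 (camera adjusted p = 0.036, adjusted p = 0.21 with an estimated correlation). PDGF and VEGF ligands and receptors counted 3 higher and 0 lower over all genes, and 6 and 1 over the list alone, of 23, with a median of 0.33 (camera adjusted p = 0.0322, adjusted p = 0.29 with an estimated correlation). Endothelial genes counted 3 higher and 1 lower over all genes, and 3 and 2 over the list alone, of 54, and were not called, with a median of 0.04, a mean of -0.08 and a test direction upward (camera adjusted p = 0.551). The Wnt list was not called without acta2 negative replicate 3 (adjusted p = 0.111), positive replicate 1 (0.24, adjusted p = 0.056) or positive replicate 3 (adjusted p = 0.0512), and had 0.26 without negative replicate 1 and 0.23 without negative replicate 2. The PDGF and VEGF list was not called without negative replicate 2 (adjusted p = 0.0575), negative replicate 3 (adjusted p = 0.121, median 0.02) or positive replicate 3 (adjusted p = 0.0637), and had 0.61 without negative replicate 1 and 0.20 without positive replicate 1. The endothelial median turned negative without any library but negative replicate 1 or positive replicate 3.

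In acta2 positive cells lens genes, mostly crystallins, had 32 of 35 lower, or 33 over the list alone, and 0 higher. The lens list had a median of -4.68 (camera adjusted p = 4.34e-24, adjusted p = 0.121 with an estimated correlation). Members included crygmx (-5.35). Photoreceptor and retina genes had 23 of 42 lower, or 33 over the list alone, with a median of -3.44 (camera adjusted p = 1.28e-20, adjusted p = 0.121 with an estimated correlation). Members included the cone arrestin gene arr3a at -3.81. Neural progenitor and glia genes had 16 of 27 lower, or 23 over the list alone, with a median of -2.55 (camera adjusted p = 9.29e-17, adjusted p = 0.0662 with an estimated correlation). Members included the myelin gene mpz at -4.79. Neuron genes counted 1 higher and 13 lower over all genes, and 1 and 25 over the list alone, of 42, with a median of -1.80 (camera adjusted p = 8.4e-11, adjusted p = 0.184 with an estimated correlation). Erythroid genes counted 1 higher and 9 lower over all genes, and 1 and 14 over the list alone, of 24, with a median of -2.20 (camera adjusted p = 6.49e-07, adjusted p = 0.236 with an estimated correlation). Members included the embryonic beta globin gene hbbe1.1 at -5.69, a near-identical paralog whose reads are of uncertain origin. Cell cycle genes counted 0 higher and 7 lower over all genes, and 0 and 17 over the list alone, of 46, with a median of -0.96 (camera adjusted p = 1.2e-10, adjusted p = 0.108 with an estimated correlation).

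Leukocyte genes counted 0 higher and 3 lower over all genes, and 0 and 3 over the list alone, of 33, with a median of -1.23 (camera adjusted p = 0.00286, adjusted p = 0.29 with an estimated correlation). Epidermis genes counted 0 higher and 1 lower over all genes, and 0 and 1 over the list alone, of 44, with a median of -1.12 (camera adjusted p = 0.00302, adjusted p = 0.497 with an estimated correlation). Cytosolic ribosomal protein genes counted 0 higher and 1 lower over all genes, and 0 and 1 over the list alone, of 82, with a median of -0.51 (camera adjusted p = 7.33e-06, adjusted p = 0.48 with an estimated correlation). Liver, gut and pancreas genes counted 0 higher and 2 lower over all genes, and 0 and 2 over the list alone, of 48, and dissociation and stress genes 1 higher and 1 lower over all genes, and 0 and 1 over the list alone, of 54. Neither list was called (camera adjusted p = 0.153 and 0.255). In acta2 positive replicate 2 the mean log2 level was 9.76 for epidermis genes, above the negative libraries (9.35 to 9.52), and 7.65 for liver, gut and pancreas genes, while the other positive libraries had 7.25 and 7.17, and 3.70 and 3.67. Without that library the medians were -1.98 for epidermis and -2.59 for liver, gut and pancreas genes, the latter then called (adjusted p = 9.11e-09), and -0.27 for ribosomal protein genes. Without positive replicate 3 the epidermis list was not called (adjusted p = 0.0728) and the liver, gut and pancreas median was 0.11, and without negative replicate 2 the ribosomal protein median was -0.29. The 2 mitochondrially encoded genes were not called over all genes, mt-rnr2 having a log2 fold change of 2.87 (adjusted p = 0.0571; list camera adjusted p = 0.0865, and adjusted p = 0.0239 without positive replicate 2). Camera called 21 of 28 lists, and fry, which asks whether a list moves one way, called 17. The counts moved by over 1.5 times without acta2 negative replicate 1 (439 higher, 335 lower), negative replicate 2 (160, 125), negative replicate 3 (202, 193), positive replicate 2 (426, 929) or positive replicate 3 (270, 353), and no list was called with an estimated correlation. Quantile normalization ended the list calls of Wnt (adjusted p = 0.117), PDGF and VEGF (adjusted p = 0.0681), cartilage and bone (adjusted p = 0.163) and tendon and fibroblast genes (adjusted p = 0.122). Other splits of these 6 libraries into 3 and 3 called up to 20 lists but 0 genes by limma.

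**Figure D2:**
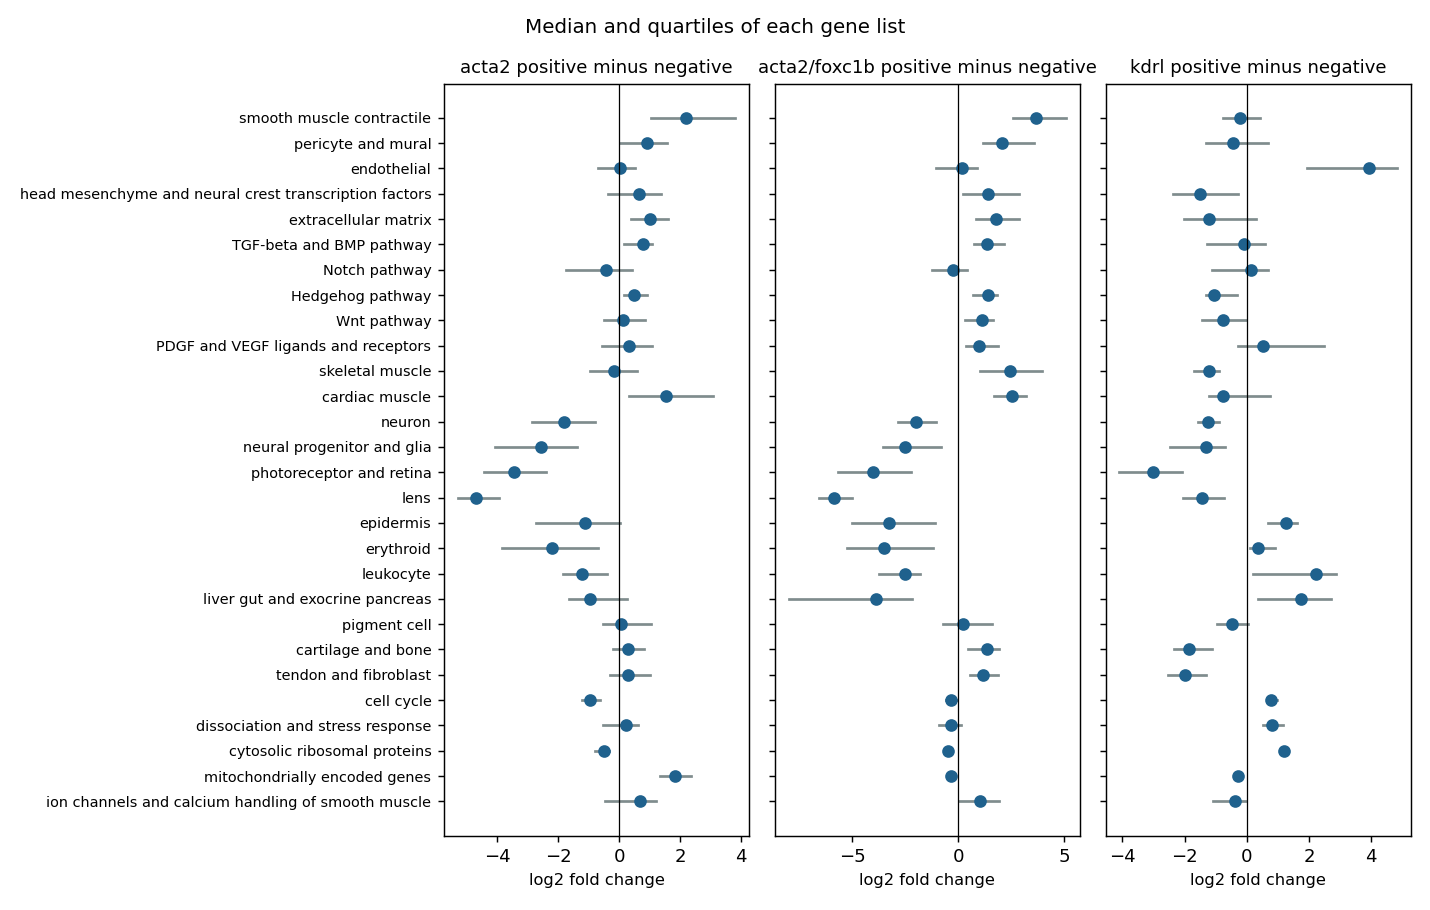
Median (point) and quartiles (line) of the log2 fold changes of positive over negative cells for each of the 28 gene lists in the acta2, acta2/foxc1b and kdrl lines. The smooth muscle contractile medians are 2.19, 3.65 and -0.21, and the endothelial median is 3.93 in the kdrl line.

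Positive and negative cells of the acta2/foxc1b line were compared for the same question in a line that also reports foxc1b. Few genes were called, among them 3 of 41 genes of the smooth muscle contractile list, all higher in the positive cells. Transcripts of acta2 were 519-fold higher, at 41102 ± 4681 normalized read counts (SD, n = 2) against 86 ± 46.3 (SD, n = 3) (log2 fold change 9.02, SE 0.63, adjusted p = 0.0272). The calls also took in tagln (8.60, adjusted p = 0.0272), cnn1b (7.27, adjusted p = 0.0323), the troponin T gene tnnt2e (6.60, adjusted p = 0.0376), the myosin light chain gene myl13 (6.57, adjusted p = 0.042) and LOC100535278, an unnamed locus chosen after its values were seen (7.37, adjusted p = 0.0272). Among 22116 tested genes, 6 were higher and 0 lower by limma, while 2532 had an unadjusted p under 0.05. EdgeR called 0 and 0, with 2723 at an unadjusted p under 0.05, and DESeq2 called 643 and 1049.

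Over the lists, contractile genes stood highest. Smooth muscle contractile genes counted 3 higher and 0 lower over all genes, and 34 and 0 over the list alone, of 41, with a median of 3.65 (camera adjusted p = 1.44e-38, adjusted p = 0.105 with an estimated correlation). Skeletal muscle genes had 0 of 57 higher over all genes and 30 higher with 1 lower over the list alone, with a median of 2.43 (camera adjusted p = 2.54e-25, adjusted p = 0.105 with an estimated correlation). In that list tnnc1b, a troponin C gene, averaged 13698 ± 10773 normalized read counts (SD, n = 2) against 151 ± 23 (SD, n = 3) (log2 fold change 6.24, adjusted p = 0.0663), and ldb3b, a Z-disc gene, had 4.61 (adjusted p = 0.0663). In the next 6 lists 0 members passed over all genes, and the counts are over the list alone. Pericyte and mural genes counted 13 higher and 0 lower of 31, with a median of 2.07 (camera adjusted p = 3.11e-11, adjusted p = 0.194 with an estimated correlation). Extracellular matrix genes counted 20 higher and 1 lower of 82, with a median of 1.77 (camera adjusted p = 3.48e-21, adjusted p = 0.194 with an estimated correlation). Cardiac muscle genes counted 3 higher and 0 lower of 23, with a median of 2.55 (camera adjusted p = 3.26e-11, adjusted p = 0.178 with an estimated correlation). Smooth muscle ion channel genes counted 6 higher and 2 lower of 39, with a median of 1.04 (camera adjusted p = 0.000113, adjusted p = 0.216 with an estimated correlation). Head mesenchyme and neural crest genes counted 2 higher and 0 lower of 47, with a median of 1.39 (camera adjusted p = 1.05e-09, adjusted p = 0.216 with an estimated correlation). TGF-beta and BMP genes counted 4 higher and 0 lower of 60, with a median of 1.37 (camera adjusted p = 2.6e-14, adjusted p = 0.149 with an estimated correlation). The ion channel median was 0.48 without acta2/foxc1b negative replicate 2 and 0.61 without positive replicate 2.

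For 5 more lists with higher medians, no member passed over all genes. The Hedgehog list had a median of 1.38 (camera adjusted p = 0.00104, adjusted p = 0.381 with an estimated correlation). The Wnt list had a median of 1.11 (camera adjusted p = 4.2e-06, adjusted p = 0.292 with an estimated correlation). The PDGF and VEGF list had a median of 0.99 (camera adjusted p = 0.000711, adjusted p = 0.359 with an estimated correlation). The cartilage and bone list had a median of 1.35 (camera adjusted p = 3.15e-05, adjusted p = 0.359 with an estimated correlation). The tendon and fibroblast list had a median of 1.17 (camera adjusted p = 0.00104, adjusted p = 0.457 with an estimated correlation). Lists of other tissues had lower medians, again with 0 members passing over all genes. Adjusted over the list alone, 33 of 37 lens genes were lower, with a median of -5.87 (camera adjusted p = 1.37e-33, adjusted p = 0.194 with an estimated correlation). So were 22 of 44 photoreceptor and retina genes, with a median of -4.03 (camera adjusted p = 5.08e-19, adjusted p = 0.299 with an estimated correlation). Of 51 liver, gut and pancreas genes, 22 were lower by that measure, with a median of -3.90 (camera adjusted p = 1.89e-18, adjusted p = 0.311 with an estimated correlation). Erythroid genes counted 2 higher and 14 lower of 24 in the same way, with a median of -3.50 (camera adjusted p = 6.8e-10, adjusted p = 0.149 with an estimated correlation). Leukocyte genes had 10 lower of 36, with a median of -2.50 (camera adjusted p = 3.11e-11, adjusted p = 0.149 with an estimated correlation). Epidermis genes had 6 lower of 44, with a median of -3.28 (camera adjusted p = 6.69e-10, adjusted p = 0.436 with an estimated correlation). Neural progenitor and glia genes had 6 lower of 27, with a median of -2.49 (camera adjusted p = 2.47e-09, adjusted p = 0.299 with an estimated correlation). Neuron genes had 0 lower of 47, with a median of -1.99 (camera adjusted p = 4.2e-06, adjusted p = 0.555 with an estimated correlation). Cytosolic ribosomal protein genes had 0 lower of 83, with a median of -0.50 (camera adjusted p = 0.0478, adjusted p = 0.871 with an estimated correlation). The endothelial list, with a median of 0.17 and a mean of -0.08, was not called (camera adjusted p = 0.588; median -0.02 without positive replicate 1), nor were the Notch, pigment cell, cell cycle, stress and mitochondrial lists. Without acta2/foxc1b negative replicate 2 the ribosomal protein median turned to 0.45 (adjusted p = 0.00027). Without that library the medians were -1.14 for epidermis, -2.44 for liver, gut and pancreas, -3.71 for neuron, 0.72 for Hedgehog, 0.64 for PDGF and VEGF and 0.54 for tendon and fibroblast genes. The cell cycle list (-0.62, adjusted p = 0.00828) and the stress list (0.40, adjusted p = 0.0295) were then called. The neuron median was -1.21 without negative replicate 1, -1.13 without negative replicate 3 and -1.26 without positive replicate 2, which also gave -1.47 for progenitor and glia genes. The stress list was called without negative replicate 3 (-0.86, adjusted p = 0.00419) and without positive replicate 2 the pigment cell (1.12, adjusted p = 0.022) and cell cycle lists (-0.47, adjusted p = 0.00943). The ribosomal protein median was -0.78 without negative replicate 1 and -1.06 without negative replicate 3, and the list was not called without positive replicate 1 (adjusted p = 0.28) or positive replicate 2 (adjusted p = 0.0535). Without positive replicate 1 the Hedgehog, PDGF and VEGF (both adjusted p = 0.072) and tendon and fibroblast lists (0.65, adjusted p = 0.428) were not called.

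The counts of this line rested on single libraries. Without acta2/foxc1b negative replicate 2, which stood apart from its replicates, limma called 335 genes higher and 439 lower. Without it, 27 of 41 smooth muscle contractile genes, 27 of 57 skeletal muscle genes and 15 of 82 extracellular matrix genes were higher over all genes. In that fit 18 of 47 neuron genes, 20 of 44 photoreceptor and retina genes, 15 of 37 lens genes and 22 of 51 liver, gut and pancreas genes were lower. In that library the liver, gut and pancreas list had a median 5.55 log2 units above the other negative libraries, the epidermis list 4.22 above, and the neuron list -4.45. There ribosomal protein genes had 2.70, mitochondrial genes 2.08 and stress genes 1.90, scaling included. Without acta2/foxc1b negative replicate 1, positive replicate 1 or positive replicate 2, limma called 0 genes in either direction, with 2096, 2866 and 1050 at an unadjusted p under 0.05. The acta2 transcript then had adjusted p = 0.0547, 0.321 and 0.989. Without negative replicate 3, myl13 and tnnt2e were not called (adjusted p = 0.081 and 0.0736). With 1 positive library left, that library was taken to vary like the negative group.

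**Figure D3:**
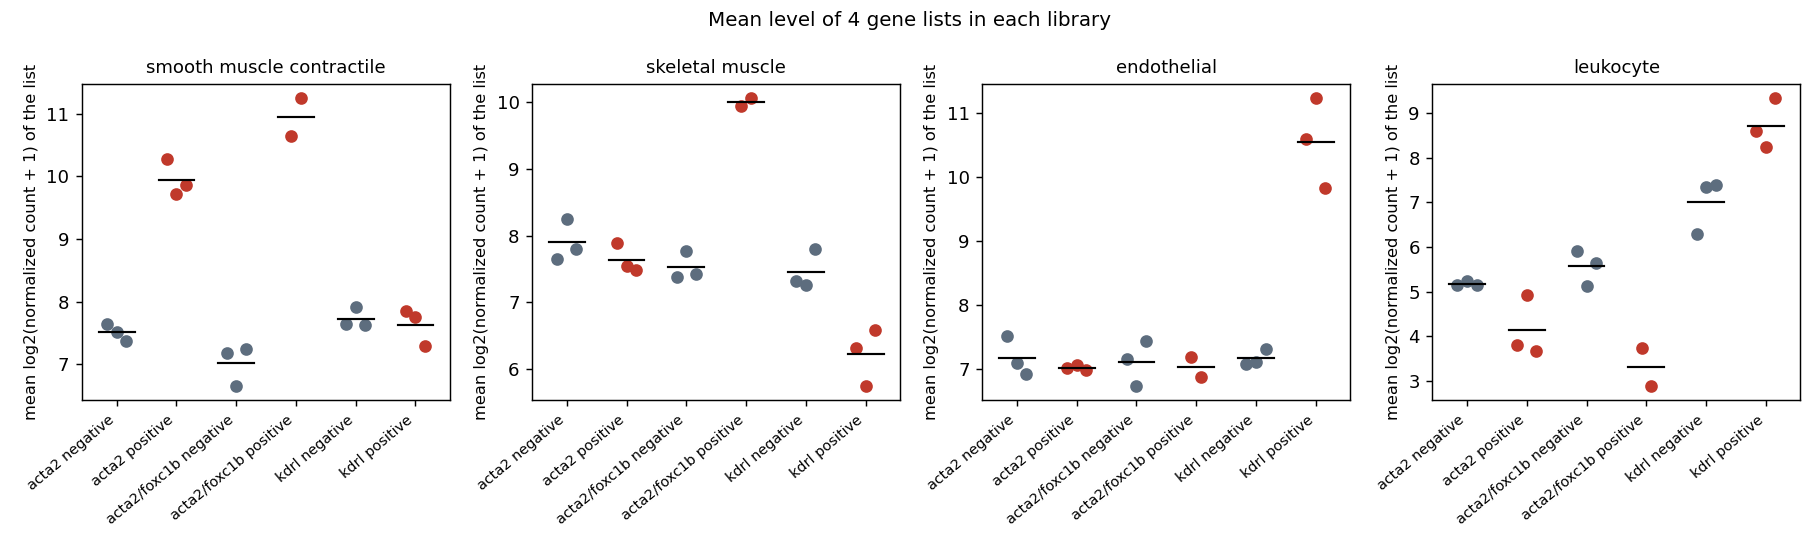
Mean log2(normalized read count + 1) of the smooth muscle contractile, skeletal muscle, endothelial and leukocyte lists, with a point for each of the 17 libraries and a line at the group mean. The skeletal muscle level is 9.94 and 10.1 in the acta2/foxc1b positive libraries and 7.38 to 7.77 in the acta2/foxc1b negative libraries.

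Positive and negative cells of the kdrl line were compared to find the genes that mark endothelial cells. Genes of the endothelial list were higher in the positive cells, 45 of 60 over all genes tested. The kdrl transcript was 38-fold higher, at 11758 ± 7048 normalized read counts (SD, n = 3) against 272 ± 36.6 (SD, n = 3) (log2 fold change 5.25, SE 0.45, adjusted p = 0.000502). Larger changes were those of pecam1, an endothelial adhesion gene, at 7111 ± 5041 normalized read counts (SD, n = 3) against 56.1 ± 9.56 (SD, n = 3) (log2 fold change 6.69, adjusted p = 0.000502), clec14a, an endothelial lectin gene (6.11), and etv2, an ETS transcription factor gene of early endothelium (6.08). Genes of the photoreceptor and retina list and of the tendon and fibroblast list were among those lower. Lower too was opn1sw1, an ultraviolet cone opsin gene, at 3003 ± 2722 normalized read counts (SD, n = 3) against 83982 ± 70748 (SD, n = 3) (log2 fold change -4.82, SE 0.74, adjusted p = 0.00564). Over 24903 tested genes, limma called 789 higher and 696 lower. With the replicate number as a block, a pairing inferred here and not in the labels, it called 1763 and 1596.

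Endothelial genes had 45 of 60 higher and 0 lower, and 51 and 0 over the list alone, with a median of 3.93 (camera adjusted p = 2.42e-43, adjusted p = 0.273 with an estimated correlation). Examples were tie1, an endothelial receptor kinase gene (5.54), lyve1b, a hyaluronan receptor gene of lymphatic and venous vessels (5.60), and the scavenger receptor gene mrc1a (5.13). PDGF and VEGF ligands and receptors counted 8 higher and 2 lower over all genes, and 8 and 4 over the list alone, of 23, with a median of 0.51 (camera adjusted p = 0.00104, adjusted p = 0.302 with an estimated correlation). Members included the VEGF receptor genes flt1 at 4.87 and flt4 at 3.34. Leukocyte genes counted 24 higher and 0 lower over all genes, and 28 and 0 over the list alone, of 43, with a median of 2.21 (camera adjusted p = 4.14e-13, adjusted p = 0.281 with an estimated correlation). Members included the lysozyme gene lyz at 10840 ± 7672 normalized read counts (SD, n = 3) against 248 ± 221 (SD, n = 3) (log2 fold change 5.74) and the plastin gene lcp1 at 3.91. Epidermis genes counted 8 higher and 0 lower over all genes, and 13 and 0 over the list alone, of 44, with a median of 1.25 (camera adjusted p = 1.12e-09, adjusted p = 0.371 with an estimated correlation). Members included the keratin genes krt17 (2.78) and cyt1 (3.37), the latter with a near-identical paralog that makes its reads uncertain. Liver, gut and pancreas genes counted 9 higher and 0 lower over all genes, and 24 and 0 over the list alone, of 52, with a median of 1.73 (camera adjusted p = 4.49e-09, adjusted p = 0.371 with an estimated correlation). With the block 18 epidermis and 23 liver, gut and pancreas genes were higher over all genes, and 29 and 25 over the list alone. Without kdrl negative replicate 1 the PDGF and VEGF median was 0.33.

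Of 82 cytosolic ribosomal protein, 46 cell cycle and 25 erythroid genes, 0 passed over all genes or over the list alone without the block. With it 1 ribosomal protein, 3 cell cycle, 3 erythroid and 12 stress genes were higher over all genes, and 77, 12, 4 and 22 over the list alone, while 1 stress gene was lower, and 2 over the list alone. The ribosomal protein list had a median of 1.19 (camera adjusted p = 1.05e-12, adjusted p = 0.484 with an estimated correlation). The cell cycle list had a median of 0.78 (camera adjusted p = 1.81e-09, adjusted p = 0.443 with an estimated correlation). Stress genes counted 1 higher and 0 lower over all genes, and 0 and 0 over the list alone, of 54, with a median of 0.81 (camera adjusted p = 0.000146, adjusted p = 0.558 with an estimated correlation). The erythroid list had a median of 0.37 (camera adjusted p = 0.0444, adjusted p = 0.558 with an estimated correlation). With the block, the erythroid list lost its call, with the same median of 0.37 and adjusted p = 0.0615, and quantile normalization ended it (adjusted p = 0.097) and that of the stress list (adjusted p = 0.0863). The erythroid list was not called without kdrl negative replicate 2 (median -0.11, adjusted p = 0.542), negative replicate 3 (0.58, adjusted p = 0.058), positive replicate 2 (0.14, adjusted p = 0.303) or positive replicate 3 (0.35, adjusted p = 0.1), and its median was 0.64 without negative replicate 1 and 1.04 without positive replicate 1. The stress list was not called without negative replicate 3 (0.21, adjusted p = 0.152), and its median was 1.44 without negative replicate 2 or positive replicate 3, 0.48 without positive replicate 1 and 0.39 without positive replicate 2. The ribosomal protein median was 0.63 without negative replicate 1.

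In kdrl positive cells tendon and fibroblast genes counted 0 higher and 11 lower over all genes, and 0 and 16 over the list alone, of 21, with a median of -2.00 (camera adjusted p = 3.36e-10, adjusted p = 0.277 with an estimated correlation). Members included thbs4b, a thrombospondin gene, at -4.50. Head mesenchyme and neural crest genes counted 0 higher and 17 lower over all genes, and 1 and 25 over the list alone, of 47, with a median of -1.51 (camera adjusted p = 4.38e-09, adjusted p = 0.273 with an estimated correlation). Members included twist2 at -3.89 and prrx1b at -3.21, both regulators of mesenchyme. Cartilage and bone genes counted 1 higher and 11 lower over all genes, and 1 and 19 over the list alone, of 29, with a median of -1.86 (camera adjusted p = 3.51e-10, adjusted p = 0.277 with an estimated correlation). Extracellular matrix genes counted 1 higher and 19 lower over all genes, and 4 and 39 over the list alone, of 83, with a median of -1.22 (camera adjusted p = 4.8e-08, adjusted p = 0.375 with an estimated correlation). Wnt genes counted 1 higher and 10 lower over all genes, and 2 and 14 over the list alone, of 57, with a median of -0.78 (camera adjusted p = 1.32e-05, adjusted p = 0.277 with an estimated correlation). Members included the secreted antagonist sfrp2 at -4.13. With the block 37 extracellular matrix, 9 Hedgehog and 26 skeletal muscle genes were lower over all genes and 23 Wnt genes over the list alone, while 4 extracellular matrix, 2 Wnt and 1 head mesenchyme genes were higher over all genes. Hedgehog genes counted 0 higher and 4 lower over all genes, and 1 and 10 over the list alone, of 19, with a median of -1.06 (camera adjusted p = 0.000195, adjusted p = 0.281 with an estimated correlation). Skeletal muscle genes counted 1 higher and 11 lower over all genes, and 1 and 26 over the list alone, of 56, with a median of -1.23 (camera adjusted p = 1.98e-11, adjusted p = 0.277 with an estimated correlation).

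Photoreceptor and retina genes had 28 of 44 lower, or 35 over the list alone, with a median of -3.01 (camera adjusted p = 1.35e-20, adjusted p = 0.281 with an estimated correlation). Neural progenitor and glia genes counted 0 higher and 10 lower over all genes, and 0 and 17 over the list alone, of 27, with a median of -1.32 (camera adjusted p = 6.83e-09, adjusted p = 0.273 with an estimated correlation). Neuron genes counted 0 higher and 3 lower over all genes, and 0 and 3 over the list alone, of 49, with a median of -1.24 (camera adjusted p = 2.06e-09, adjusted p = 0.371 with an estimated correlation). Lens genes had 0 of 36 passing either way. The lens list had a median of -1.46 (camera adjusted p = 8.75e-05, adjusted p = 0.413 with an estimated correlation). With the block 11 neuron, 16 progenitor and glia and 3 lens genes were lower over all genes, and 21, 20 and 1 over the list alone. Uncalled lists had members on both sides: smooth muscle contractile genes counted 3 higher and 2 lower over all genes, and 5 and 4 over the list alone, of 42, with myh11a higher (3.13) and a median of -0.21, which was -0.11 without negative replicate 2, -0.33 without positive replicate 1 and 0.24 without positive replicate 3. Pericyte and mural genes counted 4 higher and 4 lower over all genes, and 5 and 6 over the list alone, of 33, with the angiopoietin gene angpt2a higher (4.55) and cd248b lower (-3.28). Notch genes counted 3 higher and 6 lower over all genes, and 4 and 8 over the list alone, of 35, with a median of 0.12, a mean of -0.02 and a test direction downward. The Notch list was not called, and its median turned negative under quantile normalization and without negative replicate 3 or positive replicate 2. TGF-beta and BMP genes counted 5 higher and 8 lower over all genes, and 7 and 14 over the list alone, of 61. With the block the counts over all genes were 6 and 5 for smooth muscle contractile, 5 and 7 for pericyte and mural, 5 and 9 for Notch and 7 and 15 for TGF-beta and BMP genes. The TGF-beta and BMP, cardiac muscle, pigment cell, mitochondrial and ion channel lists were not called either. Without negative replicate 2 the lens median was -0.95, and without positive replicate 2 the pigment cell list was called (-1.08, adjusted p = 0.000268), as without negative replicate 1 (-0.65, adjusted p = 0.0139). Counts moved by over 1.5 times without kdrl negative replicate 1 (325 higher, 227 lower), negative replicate 2 (375, 213), negative replicate 3 (667, 411) or positive replicate 1 (442, 481). Camera called 20 lists, 0 of them with an estimated correlation, fry called 9, or 0 with the block, and other splits of these 6 libraries called up to 20 lists but 0 genes.

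The sort effect of the acta2/foxc1b line was set against that of the acta2 line, as a difference of differences over 11 libraries, to ask whether the double-reporter line marks a different mural profile. Skeletal muscle genes gave the largest list difference: their median was 2.92 log2 units higher in the acta2/foxc1b line, with 0 of 57 passing over all genes and 37 over the list alone (camera adjusted p = 3.45e-46, and adjusted p = 0.00408 with an estimated correlation). For smooth muscle contractile genes, 0 of 41 passed over all genes and 2 over the list alone, with a median log2 difference of 1.56 (camera adjusted p = 6.73e-15, adjusted p = 0.0732 with an estimated correlation). Head mesenchyme and neural crest genes had 0 and 4. The head mesenchyme and neural crest list had a median log2 difference of 1.39 (camera adjusted p = 2.73e-06, adjusted p = 0.337 with an estimated correlation). Liver, gut and pancreas genes had 0 and 17 lower. The liver, gut and pancreas list had a median log2 difference of -2.54 (camera adjusted p = 9.03e-17, adjusted p = 0.337 with an estimated correlation). The foxc1b gene differed by 3.54 (SE 0.87, adjusted p = 0.382) and acta2 by 1.55 (SE 0.65, adjusted p = 0.973), neither passing. Over 23438 tested genes limma called 0 in either direction, with 1169 at an unadjusted p under 0.05. EdgeR called 0 and 0, with 1780 at an unadjusted p under 0.05, and DESeq2 called 139 higher and 100 lower. Without acta2/foxc1b negative replicate 2 limma called 49 higher and 5 lower, and the median differences were 0.63 for head mesenchyme and neural crest and -0.79 for liver, gut and pancreas genes. Camera called 16 of 28 lists, 1 of them with an estimated correlation, and fry 2.

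The sort effect of the acta2 line was set against that of the kdrl line in the same way over 12 libraries, to compare mural with endothelial marking. Genes of the smooth muscle contractile and extracellular matrix lists were among those with the larger effect in the acta2 line, and genes of the endothelial and leukocyte lists in the kdrl line. The difference was 7.64 for elnb (SE 0.97, adjusted p = 0.000359), 7.44 for acta2 (SE 0.84, adjusted p = 0.000175) and 6.69 for fhl2a, a LIM domain gene of muscle (adjusted p = 0.000347). In the other direction it was -9.53 for grap2b, an adaptor gene of blood cells (adjusted p = 0.000591), -8.01 for ikzf1, a lymphoid transcription factor gene (adjusted p = 0.000814), and -3.89 for kdrl (SE 0.62, adjusted p = 0.00181). Over 25490 tested genes, limma called 714 higher and 844 lower. Smooth muscle contractile genes counted 16 higher and 0 lower over all genes, and 24 and 0 over the list alone, of 42, with a median log2 difference of 2.31 (camera adjusted p = 2.53e-18, adjusted p = 0.0256 with an estimated correlation). Extracellular matrix genes counted 34 higher and 0 lower over all genes, and 49 and 0 over the list alone, of 83, with a median log2 difference of 2.17 (camera adjusted p = 2.03e-22, adjusted p = 0.0412 with an estimated correlation). Endothelial genes counted 0 higher and 39 lower over all genes, and 0 and 46 over the list alone, of 60, with a median log2 difference of -3.79 (camera adjusted p = 6.95e-32, adjusted p = 0.0256 with an estimated correlation). Leukocyte genes counted 0 higher and 20 lower over all genes, and 1 and 26 over the list alone, of 43, with a median log2 difference of -3.35 (camera adjusted p = 3.69e-12, adjusted p = 0.0728 with an estimated correlation). Camera called 22 lists, 9 of them with an estimated correlation, or 0 with the replicate number as a block (lowest adjusted p = 0.0776), and fry 18. The lines differed in stage, in fixation, which the labels give for the kdrl cells alone, in library kit, and in having been scaled separately, so the line cannot be told apart from these. Without acta2 negative replicate 2 the counts were 454 higher and 483 lower, without kdrl negative replicate 1 they were 517 and 446, and without kdrl negative replicate 2 they were 444 and 541.

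Shared calls were counted over genes tested in both lines. Genes are not independent, so each p may be too small. All 6 genes called higher in the acta2/foxc1b line were called higher in the acta2 line (20196 genes, 0.197 expected by chance, Fisher's exact test adjusted p = 2.43e-09), and 0 were called lower in both. Of acta2 calls, 630 of 662 higher and 721 of 769 lower genes had a fold change of the same sign in the acta2/foxc1b line. In the kdrl line 321 of 664 and 480 of 762 did. Between the acta2 and kdrl lines, 53 genes were higher in both (20287 genes, 23.8 expected, adjusted p = 6.95e-08 by Fisher's exact test) and 116 lower in both (25.4 expected, exact adjusted p = 3.76e-44). The acta2/foxc1b and kdrl lines shared 0 calls by limma.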

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

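Among the tests given here, those for leukocytes, for blood of all kinds, for a share of all cells, for liver, gut and pancreas transcripts and for a positive library under a negative label, the splits that part all kdrl pairs, an estimated correlation under the block, and most lists with a library left out were chosen after the data were seen. Differences between lines in the positive against negative comparison come first, then patterns within a line or library.

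Set against the acta2 line, the acta2/foxc1b line had a higher median log2 difference of the sort effects by camera in 11 gene lists. These were skeletal muscle (2.92), smooth muscle contractile (1.56), head mesenchyme and neural crest (1.39), pericyte and mural (1.35), extracellular matrix (0.85), Wnt (0.72), cartilage and bone (0.70), TGF-beta and BMP (0.69), cell cycle (0.68), PDGF and VEGF (0.64) and cardiac muscle (0.47). The difference was lower for liver, gut and pancreas (-2.54), epidermis (-1.64), leukocyte (-1.55), lens (-1.10) and photoreceptor and retina genes (-0.95). With an estimated correlation the skeletal muscle list held (adjusted p = 0.00408), and the other lists did not pass, with adjusted p = 0.0732 for smooth muscle contractile to adjusted p = 0.740 for photoreceptor and retina genes. Without acta2/foxc1b negative replicate 2, which stood apart from its replicates, the epidermis difference turned to 0.12 (adjusted p = 0.924). The lens (-0.50, adjusted p = 0.199), PDGF and VEGF (0.09, adjusted p = 0.358), cardiac muscle (0.08, adjusted p = 0.189) and cartilage and bone differences (0.37, adjusted p = 0.183) were not called without it either. Others moved without it, to -0.79 for liver, gut and pancreas, -2.16 for photoreceptor and retina, 0.64 for pericyte and mural, 0.63 for head mesenchyme and neural crest, 0.54 for extracellular matrix and 0.43 for cell cycle genes. The neuron (-1.83, adjusted p = 2.34e-11) and ribosomal protein differences (0.90, adjusted p = 3.51e-14) were then called, and stress, Hedgehog, tendon and fibroblast, ion channel and neural progenitor genes without other single libraries.

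Calls among these lists also ended without other libraries, by camera. Photoreceptor and retina genes were not called without acta2 negative replicate 3 (-0.56, adjusted p = 0.0516), acta2 positive replicate 2 (-0.83, adjusted p = 0.134) or acta2/foxc1b negative replicate 3 (-0.22, adjusted p = 0.575). Lens genes were not called without acta2 positive replicate 2 (-0.21, adjusted p = 0.262) or acta2/foxc1b positive replicate 2 (-0.24, adjusted p = 0.581). Cardiac muscle genes were not called without acta2 positive replicate 1 (0.31, adjusted p = 0.0601) or acta2/foxc1b positive replicate 2 (0.18, adjusted p = 0.451). PDGF and VEGF genes were not called without acta2 negative replicate 1 (0.38, adjusted p = 0.0967) or acta2/foxc1b positive replicate 1 (0.66, adjusted p = 0.242), nor Wnt genes without the latter (0.54, adjusted p = 0.202). Without acta2/foxc1b negative replicate 1 the medians were -3.05 for epidermis, -1.78 for lens, 1.17 for cartilage and bone and 0.98 for PDGF and VEGF genes. Without acta2/foxc1b positive replicate 1 they were -2.48 for lens, 1.33 for cartilage and bone, 1.03 for cell cycle, 0.86 for cardiac muscle and 0.54 for extracellular matrix genes, and without its positive replicate 2 -1.01 for leukocyte and -0.59 for photoreceptor and retina genes. Epidermis genes had -0.84 without acta2 positive replicate 2, and cartilage and bone genes 1.102 without acta2 positive replicate 1.

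Between the acta2 and kdrl lines, limma called 714 genes with a higher and 844 with a lower sort effect in the acta2 line, 1558 in all. Of 100 splits within the lines, drawn without regard to kdrl pairs, the real one alone gave as many genes. The highest other gave 335. Of the 80 splits that part all kdrl pairs, 2 gave as many: the real one and that with the kdrl effect turned in sign (2227). The highest of the rest gave 208. Splits that mix the groups put the sort effects into the spread, so they cannot test whether the effects differ. A block, not used here, gave 881 and 1188. The log2 difference was 7.64 for the elastin gene elnb, 7.44 for acta2, 7.10 for the pigment cell enzyme gene aox5, 6.87 for hpdb, 6.69 for fhl2a and 6.64 for fbp2. It was -9.53 for grap2b, -8.01 for ikzf1, -7.89 for rgs13, -7.86 for ccr9a, -7.57 for the lysozyme gene lyz, -7.26 for grap2a and -3.89 for kdrl.

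By camera, the median log2 difference between these lines was higher in the acta2 line for smooth muscle contractile (2.31), extracellular matrix (2.17), cartilage and bone (2.15), tendon and fibroblast (2.06), cardiac muscle (2.03), head mesenchyme and neural crest (1.63), Hedgehog (1.497), ion channel (1.16), skeletal muscle (1.01), TGF-beta and BMP (0.94), pericyte and mural (0.91) and Wnt lists (0.77). It was lower for endothelial (-3.79), leukocyte (-3.35), epidermis (-2.92), lens (-2.79), erythroid (-2.26), liver, gut and pancreas (-2.12), ribosomal protein (-1.72), cell cycle (-1.60), neural progenitor and glia (-0.95) and stress lists (-0.53). With an estimated correlation 9 lists held, or 0 with the replicate number as a block (adjusted p of at least 0.0776): smooth muscle contractile, pericyte and mural, endothelial, head mesenchyme and neural crest, extracellular matrix, Hedgehog, Wnt, cardiac muscle, and tendon and fibroblast. The others ran from adjusted p = 0.0675 for cartilage and bone to adjusted p = 0.615 for stress genes. Of the 100 drawn splits, 7 called as many lists as the real 22, and of the 80 that part the kdrl pairs 6 did, the highest other calling 23 in both sets, so chance cannot be excluded for the number of lists. Stress genes were not called without kdrl negative replicate 3 (-0.01, adjusted p = 0.488), kdrl positive replicate 1 (-0.39, adjusted p = 0.0797) or kdrl positive replicate 2 (-0.17, adjusted p = 0.321), and had -1.09 without kdrl negative replicate 2 and -1.30 without kdrl positive replicate 3. Other medians that moved by over 1.5 times were those of liver, gut and pancreas without acta2 positive replicate 1 (-1.26), of neural progenitor and glia without kdrl negative replicate 1 (-0.51) or kdrl positive replicate 3 (-0.56), and of ion channel genes without kdrl positive replicate 3 (0.75). Notch, pigment cell and neuron genes were called without some single libraries.

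Skeletal muscle genes stood higher in acta2/foxc1b positive libraries, with 0 of 57 called by limma over all genes and a list median of 2.43 (adjusted p = 0.105 with an estimated correlation). A high level in 1 positive library alone was argued against, since the list mean of the lower positive library lay 2.17 log2 units above the highest negative library, where the negative libraries spanned 0.387. A low level in acta2/foxc1b negative replicate 2 was argued against too, as the list median was 2.44 without that library. A candidate explanation that stays open is skeletal muscle cells in the positive sort: the 10 members most abundant in the negative libraries had a median log2 fold change of 3.13, all 10 above 0, with ckmb at 134036 against 6669, ckma at 99308 against 6197 and actc1b at 36950 against 2247 normalized read counts, though none of the 10 was called by limma (adjusted p = 0.114 to 0.529). The reporter gate is the step that would remove such cells, and whether muscle cells of this line carry the reporters, a biological explanation, was not tested.

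Leukocyte genes stood higher in kdrl positive libraries, with a list median of 2.21 (camera adjusted p = 4.14e-13, adjusted p = 0.281 with an estimated correlation). Blood of all kinds was not excluded, since the erythroid list stood higher too, if less (median 0.37, upper quartile 0.889, uncalled with the block). A share of all embryo cells was argued against, since the higher of the upper quartiles of the photoreceptor and cartilage lists was -1.14. Cells of some other tissues were not excluded, since the liver, gut and pancreas list (median 1.73, 43 of 52 genes above 0) and the epidermis list (1.25, 40 of 44) stood higher too, both with adjusted p = 0.371 under an estimated correlation. Leukocytes in the positive sort may be present but the test left this open, because the marker set medians, 2.80 for neutrophil (8 of 11 higher), 1.45 for lymphoid (6 of 17) and 0.506 log2 units for macrophage genes (5 of 15), were neither all above 1 nor all below 0. Of these sets 6, 0 and 14 members also stand in the leukocyte list. The most abundant marker was apoeb at 24655 against 8822 normalized read counts (adjusted p = 0.251 by limma). Next came lyz at 10840 against 248, coro1a at 7670 against 673 and srgn at 7638 against 399. Whether the kdrl gate removes leukocytes or kdrl cells express such genes was not tested.

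The library acta2/foxc1b negative replicate 2 stood apart from its replicates, with mean Pearson r of 0.836 across genes, and 565 genes over 8-fold higher and 159 over 8-fold lower among 3644 genes with a mean of at least 1000. Liver, gut and pancreas transcripts alone stay open: the epidermis test (lower quartile 3.05 log2 units higher, scaling included) was chosen with the data seen. Undetected low-level genes were argued against by a mean r of 0.432 over 3644 genes with a mean of at least 1000 across 17 libraries. The lowest other replicate pair had 0.839. A positive library under a negative label was argued against by an acta2 value of 137, where the lowest positive library had 37792. The source stays open, with ribosomal protein genes 2.70 and stress genes 1.90 log2 units above the other negatives, scaling included. Mitochondrial genes took 4.66% of reads here, against 4.87% and 7.18% there. No biological explanation was tested.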

How the results depend on the processing

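The edgeR test on recovered reads, TMM scaling, counts within lists, fry and an estimated correlation under the block, and leaving out each library for the lists other than smooth muscle contractile, pericyte and mural, and endothelial were chosen after the data were seen. Counts are given as genes higher and genes lower, and the cause of a change was not tested unless stated.

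The smooth muscle list in both acta2 lines, the endothelial list in the kdrl line and the skeletal muscle list in the difference of the acta2 lines kept their direction and call under TMM scaling, quantile normalization and any library left out. A fold change of at least 2 removed no called gene. Of the named called genes, 58 of 100 in the acta2 line, 0 of 5 in the acta2/foxc1b line, 65 of 95 in the kdrl line and 13 of 13 in the acta2 minus kdrl difference were called with any library left out. Under every alternative tried these were 45, 0, 48 and 13.

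DESeq2 called 1343 and 1598 genes in the acta2 line, 643 and 1049 in the acta2/foxc1b line, 1599 and 1604 in the kdrl line, 139 and 100 for acta2/foxc1b minus acta2, and 1472 and 1634 for acta2 minus kdrl. Array weights gave 1388 and 1536 in the acta2 line, 498 and 753 in the acta2/foxc1b line, and 63 and 8 for acta2/foxc1b minus acta2. With all 17 samples in 1 fit the counts were 290 and 469, 883 and 868, and 291 and 194 for the acta2, acta2/foxc1b and kdrl lines, and 21 and 5 and 247 and 265 for the differences. That fit ended the calls of 36 named genes in the acta2 line, among them notch3 (adjusted p = 0.0586), and of 38 in the kdrl line, among them krt17 (adjusted p = 0.584). Quantile normalization gave 54 and 40 in the acta2/foxc1b line and 14 and 1 for acta2/foxc1b minus acta2. It moved the median of all genes from -0.06 to 0.07 in the acta2 line and from -0.11 to 0.04 in the acta2/foxc1b line.

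In the acta2/foxc1b line, genes higher numbered 11 with no filter, 11 with a pseudocount of 5 (1 lower) and 0 by edgeR, which had 2723 genes at an unadjusted p under 0.05 where limma called 6. The replicate block, which also takes the unpaired negative replicate 3 out of the estimate, gave 97 and 183 there (5 and 0 without that library alone), and 1763 and 1596 in the kdrl line, but replicate numbers did not pair the samples of the acta2 lines. It ended the erythroid call and all 9 fry calls in the kdrl line and the 9 list calls with an estimated correlation for acta2 minus kdrl, gained 7 named genes in the kdrl line and foxc1b in that difference (-1.79, adjusted p = 0.0441), and changed no other named gene or camera call there. With it, the ribosomal protein list of acta2/foxc1b minus acta2 was called lower, at -0.52 (adjusted p = 0.00359), from an uncalled median near 0 (adjusted p = 0.79). Direct comparison of the positive groups gave 39 and 7 for acta2/foxc1b minus acta2, and 3078 and 7725 for acta2 minus kdrl, the latter between libraries scaled apart. By DESeq2, shared calls were 302 and 402 for acta2 and acta2/foxc1b, 162 and 330 for acta2 and kdrl, and 59 and 162 for acta2/foxc1b and kdrl. With the block they were 51 and 74, 84 higher for acta2 and kdrl, and 8 and 25.

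The acta2 gene in the acta2/foxc1b line lost its call by edgeR (8.98, adjusted p = 0.139), and foxc1b in that line gained one with array weights (2.31, adjusted p = 0.0365). With an estimated correlation camera called 0 lists in each line, 1 for acta2/foxc1b minus acta2 and 9 for acta2 minus kdrl, against 21, 22, 20, 16 and 22. The adjusted p with an estimated correlation was 0.0662 for smooth muscle genes in the acta2 line (median 2.19), 0.105 in the acta2/foxc1b line (3.65) and 0.273 for endothelial genes in the kdrl line (3.93). That setting cannot change a median. Without the block, fry called these lists, and 4 in all in the acta2/foxc1b line, 9 in the kdrl line and 2 for acta2/foxc1b minus acta2.

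With each library left out in turn, so with fewer samples, genes higher and lower ranged over 160 to 486 and 125 to 929 in the acta2 line, 0 to 335 and 0 to 439 in the acta2/foxc1b line, and 325 to 785 and 213 to 727 in the kdrl line. For acta2/foxc1b minus acta2 they ranged over 0 to 49 and 0 to 5, and for acta2 minus kdrl over 444 to 755 and 446 to 1101. The acta2 transcript in the acta2/foxc1b line ranged over 8.64 to 9.42 and was not called without negative replicate 1 (adjusted p = 0.0547), positive replicate 1 (0.321) or positive replicate 2 (0.989). Called list medians that turned sign were those of ribosomal protein genes in the acta2/foxc1b line (-1.06 to 0.45), of epidermis genes for acta2/foxc1b minus acta2 (-3.05 to 0.12), both without acta2/foxc1b negative replicate 2, and of erythroid genes in the kdrl line (-0.11 to 1.04), without kdrl negative replicate 2. Medians of lists not called turned in every comparison. Of these, stress genes in the acta2/foxc1b line (-0.86 to 0.40) and ribosomal protein genes for acta2/foxc1b minus acta2 (-0.52 to 0.90) were called lower without negative replicate 3 and higher without negative replicate 2 of the acta2/foxc1b line.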

Other observations

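The tests given here for other splits of the libraries were planned, but the splits that part all 3 kdrl replicate pairs and the counts with a block were chosen after the data were seen.

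In kdrl positive cells, genes of the TGF-beta and BMP list (5 higher and 8 lower of 61 over all genes tested) and of the Notch list (3 and 6 of 35) passed in both directions, or 7 and 15 and 5 and 9 with the replicate number as a block, and neither list was called. The receptor gene acvrl1, which acts in vessels, had 4231 ± 3171 normalized read counts (SD, n = 3) against 405 ± 132 (SD, n = 3), a log2 fold change of 3.15 (SE 0.54, adjusted p = 0.01 by limma). The ligand genes bmp16 and tgfb1b had log2 fold changes of 3.27 and 2.51, and fstb, a follistatin gene whose product binds ligands of this family, had -3.04. The fringe gene mfng, which encodes an enzyme that modifies Notch, was higher by 3.36 (SE 0.40, adjusted p = 0.0017).

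In acta2 positive cells, smtna, a smoothelin gene, averaged 301 ± 173 normalized read counts (SD, n = 3) against 4.85 ± 2.27 (SD, n = 3), a log2 fold change of 5.61 (SE 0.66, adjusted p = 0.00474). The gluconeogenic enzyme gene fbp2 had 5.29 (SE 0.84) and pcolce2b, which encodes an enhancer of procollagen processing, 2.68 (SE 0.28). Lower was barhl2, a homeobox gene of neurons, at -6.79 (SE 0.84).

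The 6 acta2 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In 1 of them, the real one, limma called 1441 genes and camera 21 lists, where the highest other split had 0 genes and 20 lists. The 6 kdrl libraries also make 10 splits, too few in the same way. There 1 split, the real one, called 1485 genes and the highest other 0, also among the splits that part all 3 replicate pairs, and 2 of the 10 called 20 lists.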
